A study of Mus musculus with 8 samples.

How the data were processed

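CpG calls of 8 libraries from mouse embryonic stem cells were used: 3 untreated (0 h), 2 after 6 h and 3 after 12 h of 1 µM doxycycline, in medium with 50 µg/ml ascorbate. Per the labels' protocols, 10 ng of DNA were fragmented to about 300 bp, glucosylated and deaminated with an APOBEC enzyme. The libraries were sequenced in 3 runs with 150 bp chemistry. Per the file headers, the deposited files are output of the Bismark methylation extractor 0.22.3, with one line per CpG cytosine and read. The unit of the values deposited by the authors is a call letter, undeaminated or deaminated, together with the read name, chromosome and position. The submitters' processing notes name Trim Galore, Bismark 0.22.3 and the build GRCm38. Trimming and alignment settings and any removal of duplicate reads are not given in the sources used here. Among reads with at least 4 CpGs, 1.89 to 2.77% shared all positions and calls with another read of their library.

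Groups and replicate letters were taken from the sample titles. A library held 75023 to 485941 CpG calls, and its level is the percentage of these calls that are undeaminated. Levels of single libraries carry 95% Wilson intervals and mitochondrial levels exact (Clopper-Pearson) intervals, and a count of 0 is given with the share that 3 counts would make. Intervals and floors cover counting error only. Since calls on one read are not independent, standard errors clustered by read came to 123 to 146% of the binomial ones. Library levels were compared with two-sided exact permutation tests, and the trend over time with an exact permutation test of Pearson's r over the distinct assignments of the 8 libraries to the 3 times.

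Regions were tested with limma 3.58.1 in R 4.3.3. For each region and library the level in percent minus the library's level (the deviation) was fitted with 1 factor of 3 groups over all 8 libraries, weighted by the number of calls divided by the binomial variance of the library level, with moderated variances, Benjamini-Hochberg adjustment within each family of regions and a threshold of 0.05. Gains are from the same fit without subtracting the library level, and because of the weights they can differ from differences of the group means, in AY036118 also in sign. All regions of a library share its rise, so gains of different regions are not independent. The moderated variances treat them as independent, so SE and p-values of gains may be far too small. The exact permutation test of the rise itself, 12 h against 0 h, gave p = 0.1. Every adjusted p of a region is from limma unless the quasi-binomial test is named. The families were compartments, chromosomes, gene lists, genes with at least 10 calls in every library and windows of 1 Mb with at least 20 calls in every library. The contrasts of 6 h against 0 h and of 12 h against 6 h come from the same fits and were added for regions.

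Gene coordinates were taken from a gene table of GRCm38.p6, matched by symbol, that gives no strand or exons. The 2 ends of a gene therefore could not be told apart and a gene body is the span from its start to its end. The ends of protein-coding genes were taken with 1 kb on either side. The gene lists, fixed before the data were examined, were pluripotency (21 symbols), germline (20), imprinted (31), DNA methylation machinery (18), early lineage (21), housekeeping (18), very long genes of neuronal type (26) and two-cell stage (10, of which Dux was not matched). The rule for named genes, also fixed before, took the 10 largest deviations on each side among genes past the threshold with all 12 h libraries on one side of all 0 h libraries, filled by size of deviation where fewer passed, and from each list the 3 members with the most calls.

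Chosen after seeing the data were classes of reads by their number of CpG calls, windows of 10 kb with at least 200 calls (called high-copy windows here), gene ends within classes of CpGs per read, neighbouring CpGs on a read, pairs of calls on the same read, the share of reads with at least 2 undeaminated calls against that for independent calls at the level of reads with as many CpGs, and the count of gains. The minimum for a high-copy window was first 1000 calls and was lowered to 200 after low levels had been seen in 2 windows with fewer calls, so results are also given with 1000. With 200 there were 18 such windows holding 32212 calls (1.74%), and with 1000 there were 6 holding 27107 (1.47%), where a covered 10 kb window held 8.48 calls on average. The strand of a read was inferred from the order of its calls: in 447752 reads with at least 2 calls the order was never mixed, and 0 positions were seen in both orders. Which order belongs to which strand was read from adjacent positions, since the CpG cytosine of the bottom strand lies 1 base after that of the top strand: 37156 descending positions were followed by an ascending one and 1408 ascending by a descending one.

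The alternatives planned before the data were examined were leaving out each library, autosomes only, positions with a single call, positions with at most 10 calls, equal weight per position, thinning to the smallest library, the logit scale (0.5 added), median centring, no weights, the replicate letter as a block, other call minimums (5 and 20 for genes, 10 and 40 for windows) and windows of 5 Mb. Added later were a quasi-binomial test with moderated dispersion, 1 call per read, no fully undeaminated reads of at least 3 CpGs, no high-copy windows, and standardising for CpGs per read, in which the level expected from a region's CpGs per read replaces the library level. That expected level was taken from all calls of the library, those of the region included. Quasi-binomial estimates of regions with 0 undeaminated calls at 0 h diverge and are not given, though their tests enter the counts.

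Not analysed here, because no genome sequence, exons or strands were used, are the sequence contexts around CpGs and their strand pairs, flanking bases, transcription factor motif cores, promoters, exons and introns, CpG islands and repeats, and standardisation by hexamer. A test planned for tables of whole-number counts was not run either, since the files hold call letters and not counts, and the quasi-binomial test took its place.

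The limma code was tested on simulated data with the calls of the real libraries and known changes, using a spread between libraries measured in these data (1.68 times binomial for genes, 1.66 for windows) because a first simulation with an assumed constant spread called too many unchanged genes. For genes at 12 h against 0 h (346 tested, 86 changed) 0% of changes of 5 points, 48.8% of changes of 10 points and 90.7% of changes of 20 points were recovered, with 0, 6.67 and 4.88% of calls false. For windows (1202 tested, 200 changed) 7.5, 92.5 and 100% were recovered, with 0, 2.63 and 4.31% of calls false. In this simulation the variance of a level fell with its number of calls just as the weights of the fit assume. The shares of false calls thus hold only where that form is right and do not measure errors in the real data. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.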

Results

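5-Hydroxymethylcytosine (5hmC) was read at single CpG cytosines in mouse embryonic stem cells that lack TET1, TET2 and TET3, the dioxygenases that oxidise 5-methylcytosine to 5hmC. The cells carried a transposon from which doxycycline switches on the catalytic domain of mouse TET3 together with a red fluorescent reporter. APOBEC-coupled epigenetic sequencing protects 5hmC by glucosylation and then deaminates cytosine and 5-methylcytosine enzymatically, so that an undeaminated call at a CpG is read here as 5hmC plus the background of the assay. Any other form of cytosine that escapes deamination would be counted with it. There were 3 libraries of untreated cells (0 h, replicates A, B and C), 2 libraries after 6 h of 1 µM doxycycline (A and B) and 3 libraries after 12 h (A, B and C). The untreated libraries held 157700, 87030 and 102177 CpG calls, the 6 h libraries 75023 and 294209, and the 12 h libraries 454442, 485941 and 192565. Of the calls of each library, 96.2 to 97.7% lay at positions called only once in that library, so levels are given for genes, regions and groups of CpGs and not for single CpGs. The labels do not say whether the libraries came from separate cultures, and p-values then measure only the spread between these samples, which may be technical.

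The first comparison asks how much 5hmC the induced TET3 catalytic domain left in the genome after 12 h. Of all CpG calls, 24.1% ± 2.36 (SD, n = 3) were undeaminated at 12 h, against 1.13% ± 0.199 (SD, n = 3) in untreated cells, a difference of 23.0 percentage points. The 12 h libraries ranged from 22.3% (95% Wilson interval 22.2 to 22.4%) to 26.8% (26.6 to 27.0%), and the untreated libraries from 0.899% (0.854 to 0.947%) to 1.26% (1.19 to 1.33%). The mitochondrial genome, which carries little CpG methylation, stayed near the untreated level, with 22 of 1680 calls undeaminated at 12 h (1.31%, exact interval 0.822 to 1.98%) and 1 of 332 at 0 h (0.301%, 0.00763 to 1.67%). In the nuclear genome, intergenic CpGs reached 24.1% ± 2.44 (SD, n = 3), CpGs in protein-coding gene bodies 24.3% ± 2.27 and those in lncRNA gene bodies 24.4% ± 2.42. A two-sided exact permutation test of the library levels gave p = 0.1, the smallest value that 3 libraries against 3 allow (0.2 after Benjamini-Hochberg adjustment over the 4 tests of the global level). Each library was sequenced in 3 runs, and within these runs the 12 h level exceeded the 0 h level by 23.2, 22.9 and 23.1 points.

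After 6 h the level was 6.42% ± 0.212 (SD, n = 2), 5.29 points above untreated cells and 17.7 points below the 12 h libraries. The difference from untreated cells was 5.10, 5.37 and 5.23 points within the 3 runs. Two-sided exact permutation tests gave p = 0.2 for 6 h against 0 h and p = 0.2 for 12 h against 6 h, in each case the smallest value for 2 libraries against 3 (both 0.2 after adjustment over the 4 tests). Over all 8 libraries the 5hmC level rose with time in doxycycline (Pearson's r = 0.959, Spearman's rho = 0.945, both exact permutation p = 0.00357, the smallest of the 560 possible arrangements, and 0.0143 after adjustment over the 4 tests). Pearson's r stayed between 0.928 and 0.959 when each of the 15 pairs among the libraries of 0 h and 12 h was left out. These libraries lay furthest from the median time, and the pair of 6 h libraries was not left out.

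**Figure D1:**
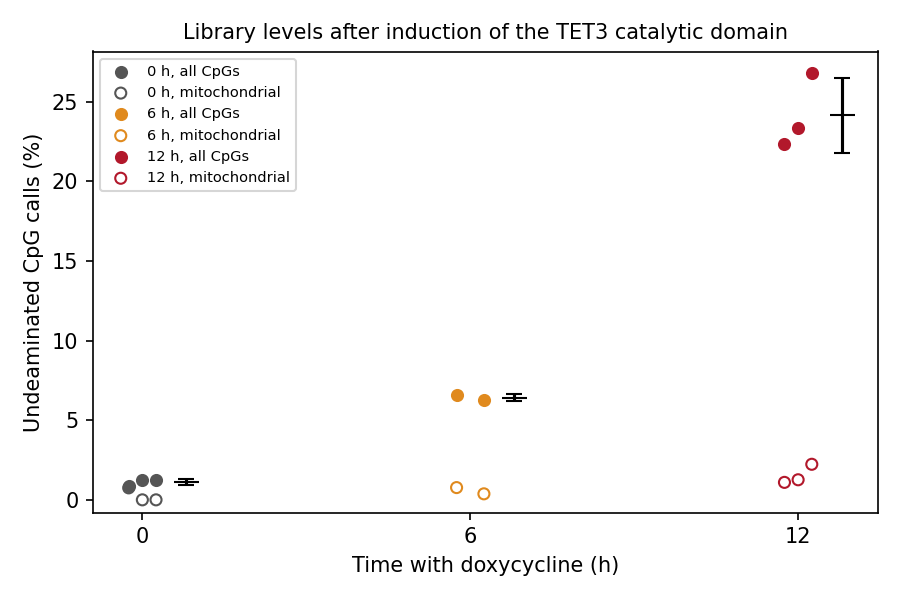
Share of undeaminated CpG calls (%, vertical axis) in each library against the time with doxycycline (h), for all CpGs (filled circles) and the mitochondrial genome (open circles), with bars for the group mean and SD of all CpGs. The 12 h libraries lie between 22.3 and 26.8% and the 6 h libraries at 6.27 and 6.57%, while no mitochondrial level exceeds 2.23%.

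Regions were then compared by how far their gain lay above or below that of the whole library. The gain was lowest where many CpGs shared a read, a stand-in for CpG density that was chosen after seeing the data. Reads with 11 or more CpGs reached 6.11% ± 1.45 (SD, n = 3) at 12 h from 1.23% ± 0.267 at 0 h, a gain of 4.34 ± 0.854 points (SE, limma adjusted p = 0.000206). Their deviation from the library gain was -18.0 ± 0.416 points (adjusted p = 1.37e-10). Reads with 8 to 10 CpGs reached 17.9% ± 2.19 (SD, n = 3), a deviation of -6.33 ± 0.184 points (adjusted p = 5.07e-10). The low level of this class lay mostly within 1 kb of the ends of protein-coding genes, with 6.70% ± 1.12 there and 23.4% ± 2.89 away from them. Reads with 11 or more CpGs were low in both places, with 3.94% ± 1.45 near gene ends and 9.77% ± 1.64 away from them. Reads with 3 CpGs reached 26.8% ± 2.50 (SD, n = 3), a deviation of 2.66 ± 0.0886 points (adjusted p = 1.06e-09). Those with 2 CpGs and with 4 to 5 CpGs lay 1.91 ± 0.0737 and 2.25 ± 0.120 points above their libraries, but the class of 4 to 5 CpGs did not pass on the logit scale (0.135, adjusted p = 0.188) or by the quasi-binomial test (0.113, adjusted p = 0.0840). All 7 classes gained 5hmC, 4 of them more and 2 of them less than the library. Reads with a single CpG lay 0.791 ± 0.0949 points above. When 1 call per read was kept they came to -0.442 points and passed below the library (limma adjusted p = 5.00e-06). They came to -0.0459 under median centring, and did not pass on the logit scale (0.0381, adjusted p = 0.630) or by the quasi-binomial test (0.0228, adjusted p = 0.608). Without fully undeaminated reads of at least 3 CpGs the class of 3 CpGs came to -0.170 points, but this alternative takes reads out by their calls and so lowers that class by design.

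Near the ends of protein-coding genes 5hmC rose less than elsewhere. CpGs within 1 kb of either end went from 1.00% ± 0.122 (SD, n = 3) at 0 h through 3.70% ± 0.136 (n = 2) at 6 h to 12.2% ± 1.59 (n = 3) at 12 h. The gain of 10.7 ± 0.475 points (SE) lay -11.7 ± 0.329 points from the library gain (limma adjusted p = 5.20e-08). Unplaced contigs deviated by -3.18 ± 0.701 points (adjusted p = 0.00864) and the mitochondrial genome by -21.2 ± 0.813 points (adjusted p = 2.09e-07). Gene bodies that are neither protein-coding nor lncRNA deviated by -1.92 ± 0.635 points (adjusted p = 0.0448), a result that most alternatives ended. Of the 9 compartments 8 gained 5hmC, and only the mitochondrial gain of 0.934 ± 0.999 points did not pass (adjusted p = 0.385). The X chromosome gained 21.7 ± 0.926 points, the Y chromosome 20.8 ± 2.99, intergenic CpGs 22.4 ± 0.735, lncRNA genes 22.5 ± 0.732 and protein-coding genes 22.5 ± 0.662. Fitted among the chromosomes, the same X and Y gains had SE of 1.45 and 4.98, so the SE depends on the regions fitted together. Standardised for CpGs per read, protein-coding gene bodies lay 0.717 ± 0.0398 points above expectation (adjusted p = 2.38e-06), and intergenic CpGs (-0.776 ± 0.0626, adjusted p = 1.96e-05), lncRNA gene bodies (-0.529 ± 0.0526, adjusted p = 5.75e-05) and the X chromosome (-0.827 ± 0.321, adjusted p = 0.0498) lay below. None of these 4 had passed before standardising. Tested among the chromosomes, the same standardised estimate of the X chromosome had an SE of 0.394 and did not pass (adjusted p = 0.126). At equal numbers of CpGs per read the gene ends gained less from 3 CpGs upwards. On reads with 8 to 10 CpGs the 12 h level was 6.70% ± 1.12 (SD, n = 3) near gene ends and 23.4% ± 2.89 away from them, a difference in gain of -16.3 ± 0.758 points (SE, adjusted p = 2.28e-07). On reads with 6 to 7 CpGs it was 12.4% ± 1.32 and 26.6% ± 2.77, a difference in gain of -13.4 ± 0.744 points (adjusted p = 5.31e-07). On reads with 1 CpG the difference was 1.63 ± 0.426 points in the other direction (adjusted p = 0.00697). Without 12 h library B it was 1.25 points and did not pass (adjusted p = 0.0622). On reads with 2 CpGs it was -0.770 ± 0.266 points (adjusted p = 0.0218) and did not pass without untreated A (-0.708), 12 h B (-0.568) or 12 h C (-0.749). On the logit scale, which compares odds and not points, the deviation of the gene ends was -0.830 (adjusted p = 0.0517). There 2 of the 9 compartments passed, the mitochondrial genome and the unplaced contigs. By the quasi-binomial test the gene ends and the unplaced contigs passed, and the mitochondrial genome did not (-1.82, adjusted p = 0.280). The unplaced contigs no longer passed without 12 h library A (-2.40 points, adjusted p = 0.0866) or under median centring (-2.25 points, adjusted p = 0.0550). The other gene bodies did not pass without untreated A (-1.93 points), either 6 h library (-1.92), 12 h A (-1.41) or 12 h B (-2.10), nor without high-copy windows (-0.696, adjusted p = 0.474), and their logit value was 0.131.

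**Figure D2:**
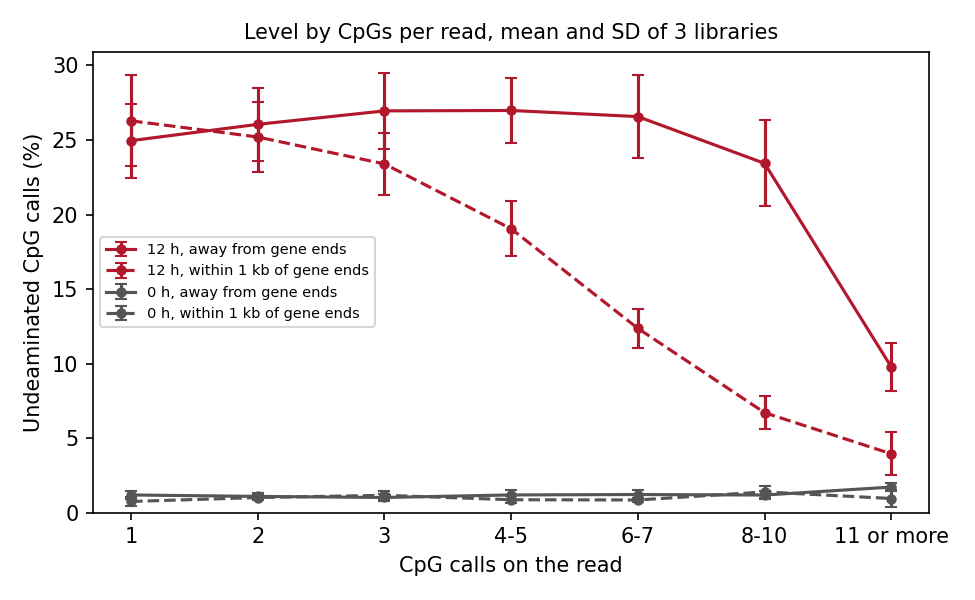
Share of undeaminated CpG calls (%, vertical axis) by the number of CpG calls on the read (horizontal axis) at 12 h and 0 h, within 1 kb of the ends of protein-coding genes (dashed) and away from them (solid), as mean and SD of 3 libraries. At 12 h the level away from gene ends stays at 23.4% or more up to 10 CpGs per read and is 9.77% at 11 or more, while near gene ends it goes from 26.3 to 3.94%.

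Of the lists of genes fixed before the data were examined, all 7 with enough calls gained 5hmC between 0 h and 12 h (limma, threshold 0.05), and each gain was compared with that of the libraries but not with other lists. Housekeeping genes, which serve basic functions in every cell, gained 11.7 ± 3.39 points (SE, adjusted p = 0.00211) and reached 13.6% ± 5.59 (SD, n = 3) from 0 of 60 calls at 0 h, which allows a share of up to 5%. Their gain lay -10.6 ± 2.29 points from that of the libraries (adjusted p = 0.00577). Polr2a, the largest subunit of RNA polymerase II, had 2 undeaminated calls of 44 at 12 h (4.55%). Actb, cytoplasmic actin, had 1 of 28 (3.57%) and Eef2, a translation elongation factor, 5 of 43 (11.6%), both without any call at 0 h. Early lineage regulators gained 14.3 ± 2.75 points (adjusted p = 3.23e-05), reached 16.6% ± 5.40 (SD, n = 3) and deviated by -7.96 ± 2.15 points (adjusted p = 0.0129). There were 11 undeaminated calls of 78 (14.1%) in Gata4, an endoderm and heart transcription factor, 13 of 73 (17.8%) in Pax6, an eye and neural regulator, and 18 of 75 (24.0%) in the homeobox gene Meis1. These 2 of the 7 lists passed as below the library gain and 0 as above, with 3 at an unadjusted p under 0.05. Standardised for CpGs per read neither passed, because the estimates shrank at similar SE, for housekeeping genes to -5.76 ± 2.19 points (adjusted p = 0.0891) and for early lineage regulators to -4.13 ± 2.23 (adjusted p = 0.219). On the logit scale 0 lists passed (1 unadjusted), by the quasi-binomial test 0 (0 unadjusted). Without 12 h library A the early lineage deviation was -4.38 points (adjusted p = 0.247).

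Pluripotency genes gained 21.1 ± 3.05 points (SE, adjusted p = 6.29e-07) and reached 23.4% ± 7.24 (SD, n = 3). Esrrb, an orphan nuclear receptor of the pluripotency network (chromosome 12, 86361117 to 86521628, GRCm38), had 0 undeaminated calls of 40 at 0 h, 5 of 76 at 6 h (6.58%) and 40 of 163 at 12 h (24.5%). Nr5a2 had 25 of 118 (21.2%) at 12 h and Tfcp2l1 11 of 39 (28.2%). Germline genes gained 25.5 ± 2.98 points (adjusted p = 2.15e-08). Among them were the piRNA pathway gene Tdrd1 with 22 of 58 calls (37.9%), Mov10l1 with 7 of 40 (17.5%) and Zcwpw1 with 4 of 29 (13.8%). Imprinted genes gained 20.6 ± 1.98 points (adjusted p = 1.06e-09), with 54 of 206 calls (26.2%) in Kcnq1, 28 of 112 (25.0%) in Igf2r and 21 of 83 (25.3%) in the overlapping noncoding Airn. Genes of the DNA methylation machinery gained 21.1 ± 2.31 points (adjusted p = 8.20e-09). Tet3 had 33 of 125 calls undeaminated at 12 h (26.4%), among which reads of the TET3 sequence in the transposon may lie. The de novo methyltransferase Dnmt3a had 30 of 94 (31.9%) and the maintenance methyltransferase Dnmt1 17 of 74 (23.0%). Genes of these lists had too few calls to be tested singly.

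Very long genes of neuronal type gained 20.8 ± 0.713 points (SE, adjusted p = 5.01e-19) and reached 22.4% ± 0.999 (SD, n = 3). Of the 26 members 19 had enough calls to be tested singly, and all 19 gained 5hmC, adjusted over all 346 genes and also 19 adjusted over the list alone. Tenm2, a teneurin, gained 24.8 ± 2.17 points (adjusted p = 3.04e-06), Cdh13, a cadherin, 22.8 ± 1.64 (adjusted p = 1.92e-06) and Wwox, an oxidoreductase at a fragile site, 21.8 ± 2.12 (adjusted p = 4.60e-06). By limma 0 of the 19 deviated from the library gain, 0 adjusted over the list alone, where the whole family of 346 genes had 49 at an unadjusted p under 0.05. Small deviations of single genes could not be called, since 0% of simulated changes of 5 points were recovered. The list as a whole deviated by -1.54 ± 0.620 points (adjusted p = 0.0727). Standardised for CpGs per read it deviated by -2.73 ± 0.657 points (adjusted p = 0.0143). Genes of the two-cell stage were not testable, since 3 of the 10 listed symbols had calls. At 6 h the gains of 2 lists passed, those of the imprinted genes (6.91 ± 1.87 points, adjusted p = 0.00408) and the long neuronal genes (4.92 ± 0.733 points, adjusted p = 4.94e-06).

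Of the 346 genes with at least 10 calls in every library, 342 gained 5hmC between 0 h and 12 h (limma, adjusted p under 0.05) and 0 lost it. Ptpn14, a cytoplasmic tyrosine phosphatase (chromosome 1, 189728216 to 189876695), reached 39.6% ± 4.90 (SD, n = 3) at 12 h, 16.2 ± 2.67 points above the library gain (SE, adjusted p = 0.0126). Cmip, an adaptor protein of T-cell signalling (chromosome 8, 117257019 to 117461506), reached 35.2% ± 4.45 from 0 of 77 calls at 0 h, which allows up to 3.90%. It lay 11.4 ± 2.02 points above the library gain (adjusted p = 0.0128). Below the library gain lay the ribosomal RNA pseudogene Rn18s-rs5 (chromosome 17, 39846354 to 39848202), which reached only 3.29% ± 0.771 from 0 of 438 calls (allowing up to 0.685%) and deviated by -18.6 ± 1.18 points (adjusted p = 4.83e-06). The adjoining lncRNA AY036118 (39848112 to 39898385) had 4.29% ± 5.92 at 0 h and 6.26% ± 6.18 at 12 h (deviation -25.0 ± 4.87 points, adjusted p = 0.0229). Its gain was -2.65 ± 4.78 points with weights and 1.96 without, so its direction is open, and without weights its deviation was -21.1 points. Cdk8, a kinase of the Mediator complex (chromosome 5, 146230795 to 146302874), reached 10.5% ± 2.05 (deviation -12.5 ± 2.56 points, adjusted p = 0.0284). Filip1l (chromosome 16, 57353277 to 57572804) reached 9.30% ± 2.96 and Cmss1 (57301999 to 57606867), which overlaps it and shares its calls, 10.3% ± 2.82. Their deviations were -12.2 ± 2.02 and -11.2 ± 1.98 points (adjusted p = 0.0126 and 0.0128). In each of these 7 genes all 3 libraries at 12 h lay on the side given.

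Of the genes named by size that did not pass, Abat, the GABA transaminase, had a deviation of 18.5 ± 4.18 points (adjusted p = 0.0520) with 41.3% ± 1.11 (SD, n = 3) at 12 h. The values of Ptpn13, Atp8a1, Cracdl, Sergef, Cit, Wwc1 and Arhgap32 lay between 11.1 and 14.4 points, and when each library was left out they ran from 5.65 (Ptpn13 without 12 h B) to 20.0 (Ptpn13 without 12 h A). Ptpn13 and Cracdl (18.4 points) passed without 12 h A, Cit without 12 h C (13.9) and with the replicate letter as a block (12.0), and Abat without either 6 h library (18.5), without weights (18.2) and without fully undeaminated reads (19.6). Without untreated A Arhgap32 came to 6.30 points, without 12 h A Cit to 7.54, and without untreated C Cfap77 to -2.26. On the lower side Hdac9 had -10.2 ± 3.99 points, Cfap77 -8.78 ± 7.98, Opcml -8.42 ± 2.60 and Grin2b -7.72 ± 4.05. The value of Bcl11b, -19.8 ± 25.7 points, rests on untreated library B and is 0.428 points without it, though it passed with the block (-27.1). Without 12 h library B only Rn18s-rs5 of the 7 genes passed. Ptpn14 (12.8 points), Cmip (10.7), Filip1l (-10.9) and Cmss1 (-9.85) did not, nor did Cdk8 (-13.6) and AY036118 (-24.1). Cdk8 also failed without untreated A (-12.3), B (-12.6) or C (-12.5) and without 12 h A (-12.0) or C (-11.9), and AY036118 without either 6 h library (-25.0) and without 12 h A (-24.5) or C (-26.0). On the logit scale 0 genes passed (62 unadjusted). There Cmip, Abat, Ptpn13, Atp8a1, Cracdl and Sergef came out below 0, but they had 0 undeaminated calls at 0 h, so that the 0.5 added sets their starting level and the sign says nothing about them. Wwc1 and Arhgap32, with undeaminated calls in 1 untreated library, also came out below 0. The quasi-binomial test called AY036118 (-3.69, adjusted p = 0.00431) and Bcl11b (-3.31, adjusted p = 0.0227), so of the 7 genes only AY036118. It could not have called Rn18s-rs5, Cdk8, Filip1l or Cmss1 as below the library. With 0 undeaminated calls at 0 h their estimates diverge upwards, as does that of Cmip. With 1 call per read 0 genes passed, and Ptpn14 came to 7.41 points (adjusted p = 0.430). Thinned to the smallest library it came to 23.4 points (adjusted p = 0.0515). Filip1l and Cmss1 changed sign when only positions called once were kept (2.68 and 3.39 points) or when levels were standardised for CpGs per read (1.87 and 2.07 points). Within windows of 10 kb that held at least 200 calls, the 12 h level was 3.87% in Cdk8 and 5.33% in Filip1l and Cmss1. Outside these windows it was 35.9% (14 of 39 calls), 38.2% (21 of 55) and 36.0% (27 of 75).

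**Figure D3:**
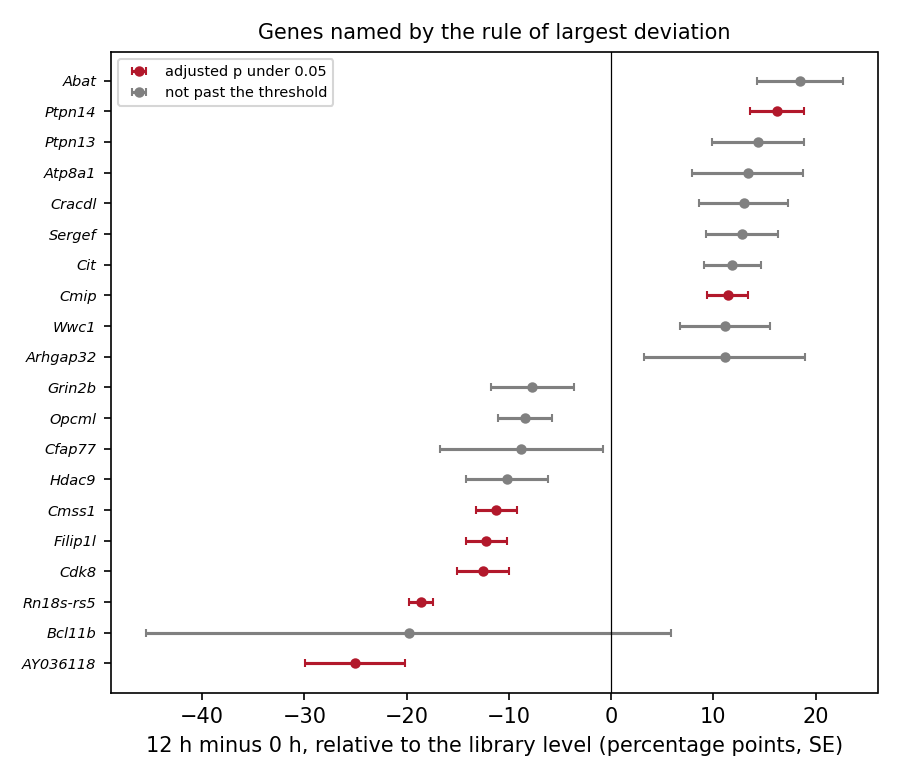
Difference between the 12 h and 0 h levels relative to the library level (percentage points, horizontal axis, with SE) of the 20 genes named by size of deviation, in red where the limma adjusted p is under 0.05. Ptpn14 at 16.2 and Cmip at 11.4 points passed above 0, and 5 genes from Cmss1 at -11.2 to AY036118 at -25.0 points passed below.

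All 21 nuclear chromosomes gained 5hmC. Chromosome 17 gained 20.5 ± 0.817 points (SE) and reached 22.6% ± 2.81 (SD, n = 3), a deviation of -1.85 ± 0.215 points (limma adjusted p = 0.000154). Chromosome 14 lay 0.999 ± 0.242 points above the library gain (adjusted p = 0.0226), chromosome 15 0.800 ± 0.247, chromosome 8 0.723 ± 0.211 and chromosome 16 0.651 ± 0.196 (adjusted p = 0.0384 each). Chromosome 14 did not pass without untreated B (1.00 points) or 12 h B (0.604). Chromosome 15 did not pass without untreated B (0.734) or C (0.797), either 6 h library (0.800), 12 h B (0.537) or 12 h C (0.741). Chromosome 8 did not pass without untreated A (0.649) or B (0.686), either 6 h library (0.723) or 12 h A (0.851), B (0.733) or C (0.625), and chromosome 16 not without untreated B or C (0.665 each), either 6 h library (0.651) or 12 h A (0.651), B (0.626) or C (0.668). Of the 1202 windows of 1 Mb with at least 20 calls in every library 1201 gained 5hmC, and 2 deviated from the library gain. The window at 39000001 to 40000000 on chromosome 17, which holds Rn18s-rs5 and AY036118, reached 5.18% ± 1.47 (SD, n = 3), a deviation of -20.5 ± 1.26 points (adjusted p = 1.23e-07). The window at 98000001 to 99000000 on chromosome 2 reached 29.9% ± 3.80, a deviation of 5.17 ± 0.882 points (adjusted p = 0.0215). Of their calls 97.7% and 98.6% fell in windows of 10 kb with at least 200 calls. Standardised for CpGs per read neither 1 Mb window passed, with estimates that shrank to -6.22 ± 1.11 points (adjusted p = 0.0745) on chromosome 17 and 3.22 ± 0.844 (adjusted p = 0.321) on chromosome 2. The 10 kb windows that hold most of their calls still passed among the 12 high-copy windows tested, at -6.23 ± 1.34 points (adjusted p = 0.0137) and 3.32 ± 0.983 (adjusted p = 0.0474), so the loss depends also on the number of windows tested. Without such windows of 10 kb 0 chromosomes (6 unadjusted) and 0 windows (135 unadjusted) passed, with chromosome 17 then 0.134 points above the library gain. By the quasi-binomial test 0 chromosomes (2 unadjusted) and 3 windows passed, all 3 below. The window on chromosome 2 did not pass without either 6 h library (5.17 points) or without 12 h library A (5.05), B (5.96) or C (4.63).

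Some of the regions that lagged at 12 h already lay lower at 6 h. Reads with 11 or more CpGs deviated by -4.55 ± 0.382 points (SE, limma adjusted p = 8.01e-06), gene ends by -2.66 ± 0.317 (adjusted p = 0.000720) and chromosome 17 by -1.42 ± 0.211 (adjusted p = 0.00125). The other gene bodies did not pass at 6 h (-1.18 ± 0.633 points, adjusted p = 0.241). Gains at 6 h passed in 20 of the 21 chromosomes, 22 of the 346 genes and 576 of the 1202 windows, and 0 features of any family lost 5hmC. Among genes 0 deviated from the library gain at 6 h (limma, 23 at an unadjusted p under 0.05), and among lists 0 (1 unadjusted). Between 6 h and 12 h 317 genes and 1189 windows gained 5hmC.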

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

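All tests of explanations in this part, and the classes of CpGs per read and the high-copy windows they use, were chosen after the results were seen, as were the comparisons of the deviations at 12 h with those at 6 h. The deviation from the library level at 12 h differed from that at 6 h (limma, same fit, adjusted p under 0.05) in the classes, regions and gene of the following paragraph and at gene ends. It did not pass for Cdk8, Filip1l, Cmss1 and AY036118 (adjusted p of 0.326 to 0.499). These deviations are in points from a library level that rose from 6.42% at 6 h to 24.1% at 12 h. A region that gained a constant share of the library gain at both times would therefore also move. The comparisons cannot tell such scaling from a change over time.

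Reads with 11 or more CpGs moved by a further -13.5 ± 0.517 points (SE) relative to their libraries between 6 h and 12 h, and reads with 8 to 10 CpGs by -5.42 ± 0.235. Reads with 1, 2, 3 and 4 to 5 CpGs moved by 0.791 ± 0.125, 1.45 ± 0.0965, 1.80 ± 0.116 and 1.27 ± 0.155 points. The mitochondrial genome moved by -16.1 ± 1.11 points, while its own level changed by less than the test could call. Rn18s-rs5 moved by -14.9 ± 1.48 points (adjusted p = 0.000400), the 10 kb window at 39840001 on chromosome 17 that holds it by -13.7 ± 1.93, and the 1 Mb window at 39000001 around it by -13.5 ± 1.54. The 10 kb window at 57390001 on chromosome 16, within Cmss1 and Filip1l, moved by -11.6 ± 3.14 points, and the window at 98660001 on chromosome 2, with no annotated gene, by 5.30 ± 1.33.

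Gene ends moved by -9.03 ± 0.419 points relative to their libraries between 6 h and 12 h, and their deviation at 12 h against 0 h was -11.7 points. Many CpGs per read do not account for all of it, since -4.55 ± 0.153 points (SE, adjusted p = 1.66e-07) were left after standardising for CpGs per read. The expected level came from all calls, including those near gene ends. At 12 h these held 49283 calls on reads with 11 or more CpGs, against 29610 away from gene ends. Their lower level is thus partly subtracted from itself, and the part owed to CpGs per read cannot be read from the remainder. The share of calls near gene ends was 11.5 to 11.6% in the libraries at 0 h, 12.3% on average at 6 h and 10.9 to 11.1% at 12 h, below every untreated library. A loss of undeaminated reads as the whole cause would have needed 9.98%, so it can account for no more than part. Less 5-methylcytosine near gene ends before induction, or less access of the enzyme to them, may each leave such a pattern, and neither was measured in these libraries.

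The 5 genes below the library gain overlap windows with many calls, which may hold reads from repeated copies placed in 1 position. For Cdk8, Filip1l and Cmss1 the calls outside the high-copy windows lay 14.1 ± 5.65 points (SD of 3 libraries, 114 calls) above the library level at 12 h, while the minimum of 1000 calls used first leaves out 0 of their calls and gives -13.6 ± 3.31 (607 calls). Repeated copies and a low level of these windows themselves cannot be told apart, because neither would lower the calls outside and the minimum was lowered after low levels had been seen there, and for Rn18s-rs5 and AY036118 because only 2 calls lay outside. The deviation of Rn18s-rs5 was -8.07 ± 1.09 points after standardising (adjusted p = 0.0114). Standardising used classes of CpGs per read, and the class with the most CpGs has no upper limit. Levels fell steeply towards that class, and the number of CpGs per read within it was not matched. Whether many CpGs per read account for all of the deviation of Rn18s-rs5 thus cannot be told from the remainder. For AY036118, Cdk8, Filip1l and Cmss1 the standardised deviations had a median of -0.798 points and a lowest value of -8.18 (AY036118, ± 4.78), none passed, and CpGs per read are a candidate explanation of their lower gain.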

How the results depend on the processing

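The alternatives without high-copy windows, with 1 call per read, without fully undeaminated reads, standardised for CpGs per read and with the quasi-binomial test were chosen after seeing the data, as were the counts of gains, of classes of CpGs per read and of high-copy windows. The global differences kept their direction under every alternative run, and the trend stayed past the threshold, while the pairwise permutation tests cannot reach 0.05 with so few libraries. Leaving out each library gave 21.7 to 23.9 points for 12 h against 0 h, 5.14 to 5.44 for 6 h against 0 h, 16.4 to 18.6 for 12 h against 6 h and r of 0.949 to 0.974. Of the counts and global values under an alternative 263 stayed within 1.5 times or on their side of the threshold, 61 were lower and 5 higher. Of the single regions, genes and other values 1600 were the same, 164 lost and 14 gained a call, 3 moved and 33 reversed. The cause of a change was not tested unless one is given. Leaving out either 6 h library leaves 1 sample at 6 h, which is assumed to vary like the other groups.

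Counts of regions past the threshold at 12 h against 0 h were 4 for compartments, 5 for chromosomes, 2 for lists, 7 for genes, 2 for windows and 4 for high-copy windows. Positions with a single call gave 0 chromosomes (6 at an unadjusted p under 0.05, limma), 3 genes (2 above, 1 below), 1 window and 1 high-copy window. Positions with at most 10 calls gave 1 window. Thinning gave 2 chromosomes, 0 lists (1 unadjusted), 1 gene, 1 window and 2 high-copy windows. It also gave 163 gaining genes against 342, since only 173 could be tested. With 1 call per read there were 9 compartments (1 above, 8 below), 1 list, 0 genes (14 unadjusted), 1 window and 2 high-copy windows. There were 80 gaining genes and 448 gaining windows against 1201, again with fewer tested. Autosomes alone left 1 compartment past the threshold and 5 gaining against 8, since only 5 remained. The logit scale gave 2 compartments, 0 chromosomes (2 unadjusted), 0 lists (1), 0 genes (62), 0 windows (62) and 2 high-copy windows. Median centring gave 3 compartments above and 2 below against 0 and 4, 1 and 1 chromosomes against 4 above and 1 below, 0 and 1 windows against 1 and 1, and 3 and 3 classes of CpGs per read against 4 and 2. In all, 2 chromosomes and 1 window passed. Without weights 4 genes (2 above, 2 below) and 1 window passed. Standardising for CpGs per read gave 7 compartments (protein-coding gene bodies above, and intergenic CpGs, lncRNA gene bodies, the X chromosome, gene ends, contigs and the mitochondrial genome below), 0 chromosomes (8 unadjusted), 1 list, 3 genes (2 above, 1 below), 0 windows (105) and 2 high-copy windows. The 1 list was the very long neuronal genes (-2.73 ± 0.657 points, adjusted p = 0.0143), which had not passed before, while housekeeping (-5.76) and early lineage (-4.13) no longer passed. The quasi-binomial test gave 2 compartments, 0 chromosomes (2), 0 lists (0), 2 genes, AY036118 and Bcl11b, both below, and 1 high-copy window. Without high-copy windows 0 chromosomes (6), 2 genes, both above, and 0 windows (135) passed. With the minimum of 1000 calls there were 0 chromosomes (6), 0 windows (136) and 2 high-copy windows. At least 5 calls per library gave 11 genes (4 above, 7 below), and at least 10 calls 1 window.

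Leaving out each library gave 2 to 4 compartments (2 without 12 h A), 1 to 4 chromosomes (1 without untreated B or 12 h B, 2 without 6 h A, 6 h B or 12 h C, 3 without untreated C or 12 h A), 1 to 3 lists (1 without 12 h A), 1 to 8 genes (1 without 12 h B) and 1 to 4 windows (4 without untreated A, 1 without either 6 h or any 12 h library). It gave 4 high-copy windows, 6 to 7 classes of CpGs per read, 337 to 343 gaining genes and 1197 to 1202 gaining windows.

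The labels do not say whether the replicate letters pair libraries across times. The deviations of the 7 same-letter pairs of libraries correlated by 7.15e-05 to 0.0652 (mean 0.0271), none over 0.1. The 14 other pairs had a mean of -0.0136, and 7 of the 8 libraries lay closest to a library of their own letter. These deviations were taken from group means, so they sum to 0 within a group and the 2 libraries of 6 h mirror each other. The contrast between the sets of pairs and the 7 of 8 are thus largely arithmetic and no separate evidence of pairing. A weak pairing is not excluded. With the letter as a block 17 windows (9 above, 8 below) and 10 genes passed against 2 and 7, the gain of Bcl11b was -4.54 points, and chromosome 15 no longer passed (0.815 points, adjusted p = 0.0568).

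Reversed values were, for reads with 1 CpG, -0.442 with 1 call per read, which passed below, and -0.0459 under median centring, which did not pass. For reads with 3 CpGs the value was -0.170 without fully undeaminated reads, an alternative that lowers this class by design. Chromosome 17 came to 0.134 points without high-copy windows and 0.146 with the minimum of 1000. Filip1l came to 2.68 and Cmss1 to 3.39 with positions called once and to 1.87 and 2.07 when standardised, and the window at 98000001 on chromosome 2 to -0.316 with positions called once. On the logit scale the other gene bodies came to 0.131 and chromosome 8 to -0.0179, which had passed before, and Wwc1 to -0.647 and Arhgap32 to -0.787, which had not. Values below 0 for Cmip (-0.0231), Abat (-0.307), Ptpn13 (-0.707), Atp8a1 (-0.391), Cracdl (-0.672) and Sergef (-0.257) are no reversals in the data, since these genes had 0 undeaminated calls at 0 h and the 0.5 added sets their starting level. The quasi-binomial estimates (log odds) were -0.0340 for chromosome 8, -0.0111 for the high-copy window at 98660001 and -0.00507 for the 1 Mb window around it, -0.382 for Wwc1 and -0.804 for Arhgap32. The deviation of Bcl11b ran from -36.8 to 0.428 points and its gain from -14.3 to 23.2 when each library was left out. The gain of AY036118 ran from -4.57 to 3.12, with 2.55 for positions called once and 1.96 without weights. Among regions that did not pass, the sign of the deviation changed under some alternative in 1 of 1 classes of CpGs per read, 5 of 5 compartments, 13 of 16 chromosomes, 5 of 5 lists, 8 of 8 high-copy windows and 10 of 16 named genes. Depth limits single genes and windows, since changes of 5 points were recovered in 0% of simulated genes and 7.5% of windows. Contexts, motifs, promoters, islands, repeats, hexamer standardisation and the planned test of whole-number counts were not run.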

Other observations

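The tests in this part were all chosen after the results were seen. Undeaminated calls came in clusters on the same reads. Reads with at least 2 undeaminated calls made up 0.701% ± 0.196 (SD, n = 3) of reads with 2 or more CpGs at 0 h, 3.73% ± 0.0282 (n = 2) at 6 h and 19.7% ± 2.26 (n = 3) at 12 h, where independent calls at the same levels would give 17.0% ± 2.58. At 12 h CpGs 2 bp apart on a read were both undeaminated with an odds ratio of 9.63 against independent calls, and CpGs 81 to 150 bp apart with 3.43. In reads with 2 to 5 CpGs these were 4.04 and 2.04. The odds ratios were 21.5 and 4.70 at 6 h and 230 and 24.9 at 0 h, where the level is near the background.

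Of neighbouring CpGs on a read, the downstream member, in the direction inferred from the order of calls, gained more than the upstream member at 3 of the 11 distances tested. The difference was 1.01 ± 0.319 points (SE, limma adjusted p = 0.0298) at 2 bp, 1.72 ± 0.380 (adjusted p = 0.00414) at 3 bp and 1.53 ± 0.337 (adjusted p = 0.00414) at 12 bp, in all 3 libraries at 12 h. Without 12 h library B the differences at 2 and 3 bp were 0.761 and 1.17 points and did not pass (adjusted p = 0.202 and 0.0550). At 2 bp the call also ended without untreated A (0.924 points) or B (0.979), either 6 h library (1.01) or 12 h C (0.878).

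Clusters on the same read were weighed against 3 explanations. Failed deamination of single molecules at the rate of the untreated libraries would add at most the share of reads with at least 2 undeaminated calls seen there, 0.863% in the highest library, and the excess over independent calls at 12 h was 2.29 points in the lowest library. Differences between loci that all libraries share would make the same CpG alike between libraries, and the highest odds ratio between 12 h libraries was 2.10 against 9.34 in the lowest library within reads at 2 bp, both without high-copy windows. These sets were not matched for CpGs per read. At 81 to 150 bp the lowest library without high-copy windows had 3.24, but reads with 2 to 5 CpGs had 2.01 to 2.08, no higher than between libraries. Shared loci are thus not set apart from the clusters at that distance. Differences between cells in the amount of enzyme, as the only cause, would give the same odds ratio at every distance if the pairs came from like loci. In reads with 2 to 5 CpGs the lowest library at 2 bp had 3.81 against 2.08 in the highest at 81 to 150 bp. Pairs at different distances were not matched for locus, so the fall with distance cannot exclude cell differences. They may also hold part of the clusters, including the 2.01 to 2.08 at 81 to 150 bp. Action of the TET3 domain on neighbouring CpGs in turn, methylation that differs between molecules, and local failure of the deaminase where 5hmC is frequent may each add to the clusters and were not tested.

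Each count of 12 h against 0 h was recomputed over the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. The real split gave 7 genes and the highest other split 1, for classes of CpGs per read 6 and 0, compartments 4 and 0, chromosomes 5 and 0, lists 2 and 0, high-copy windows 4 and 1, and 1 Mb windows 2 and 3. For gains the real split gave 342 genes against 1, and 7 classes of CpGs per read, 8 compartments, 21 chromosomes, 7 lists and 1201 windows against 0 each, but every other split mixes 0 h and 12 h libraries in both groups, which leaves hardly any gain to be called and makes this count void. For neighbouring CpGs the real split gave 3 distances against 0, and for gene ends within classes of CpGs per read 7 classes against 0. For these counts and for the deviations above, the same mixing puts any difference between 0 h and 12 h inside both groups. Low counts in the other splits were thus largely fixed in advance, and no conclusion is drawn from them.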
